A study of Mus musculus with 18 samples.

How the data were processed

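The data are RNA sequencing of mouse kidney after unilateral ischemia and reperfusion (UIR), in which the pedicle of the right kidney is clamped and then released, or after a sham operation. The labels name 18 libraries of C57BL/6 mice, 3 biological replicates in each of 6 groups, from sham and UIR mice at 1, 3 and 21 days after surgery. They name neither the kidney sequenced nor the sex.

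The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 20825 genes, named by Entrez Gene ID and symbol, in 18 columns. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mm9 build are named, per the submitters' processing notes, without the role of each. Further scaling of the deposited FPKM values by the authors is not given in the sources used here. Every column matched the title of 1 sample, and 2 column names lacked the word FPKM. Symbols stored as dates (27) were restored through their Entrez IDs, and 20766 IDs were found in the RefSeq gene table. The annotation used here is of another build than mm9, so no coordinates are given. The lowest value above 0 is 0.01 FPKM, and no library pair held identical values. Read counts are not used here and the depth of each library is unknown, so no counting interval is given, and a gene listed at 0 has no fold.

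Genes entered the test where FPKM was at least 1 in at least 3 of the 18 libraries, which left 14716. Values were analysed as log2(FPKM + 1). On this scale folds understate changes of genes with low FPKM. limma 3.58.1 in R 4.3.3 fitted a mean per group to all 18 libraries (12 residual degrees of freedom), with the variance trend in its moderation. Each contrast was tested with limma, two-sided, with Benjamini-Hochberg adjustment over the genes tested, and the threshold was an adjusted p of 0.05. The contrasts were UIR minus sham at each day, the later minus the earlier of these effects for each pair of days, and the later minus the earlier sham group. Log2 folds are given ± SE, and levels are mean FPKM ± SD of 3 libraries. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so genes are tested only by the model across all genes. Beside the counts stands the share of genes whose 3 libraries of 1 group all lay above or below the 3 of the other, which chance would give for 10% of genes.

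Before the data were examined, 32 lists holding 626 genes were written from general knowledge of kidney biology, of which 623 were in the table and 572 passed the filter. camera, a limma test that compares a list with all other genes, was run with its preset correlation of 0.01 and adjusted over 25 lists. Check lists of circadian clock, androgen-dependent kidney, erythroid and adipose tissue genes were tested apart from these. The adrenal gland, skeletal muscle and Y-linked check lists had under 5 members past the filter and were not tested. camera was also run with the correlation estimated from the libraries, with its adjusted p named as such. Except for 1 list in 1 comparison between days, no call among the 25 lists held with an estimated correlation. Counts of list members are at the threshold over all genes, and counts adjusted over the list alone are named as such.

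The genes named follow a rule of the same time. At each day they are the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 5 FPKM over the 18 libraries and no overlap of the 3 UIR and 3 sham values, without model or clone identifiers. To these come 20 markers in every comparison, namely Havcr1, Lcn2, Krt20, Sox9, Vcam1, Slc34a1, Slc5a2, Umod, Hnf4a, Ppargc1a, Cdkn1a, Mki67, Ccl2, C3, Adgre1, Cd3e, Cd79a, Col1a1, Fn1 and Acta2. For each list described, up to 4 members with the largest change in its direction are named, and members that moved the other way where needed. For differences between days and between sham groups the 5 largest changes in each direction are named, for differences between days without the condition on overlap. Some genes that this rule would name are not reported here. Genes with near-identical copies, whose reads the quantification may have divided between them, are uncertain as single genes. These are Hspa1a and Hspa1b, Cyp2a4 and Cyp2a5, Lyz1 and Lyz2, and members of the Cyp4a, Serpina1, Hsd3b, Hist1h2a, Gsta and hemoglobin families, and the pseudogene Rpl14-ps1.

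The test was checked on simulated data with 200 of 14716 genes and 1 planted list changed. It recovered 83.6%, 86.6% and 85.1% of 2-fold changes at days 1, 3 and 21, with 7.8%, 4.1% and 5.3% of calls false. Of 2-fold differences of effects it recovered 76.1%, 73.1% and 79.1% for days 1 and 3, 3 and 21, and 1 and 21. For sham groups they were 94.0%, 86.6% and 85.1%. Far more genes were called in the data, so their false share stays unknown. Of 24 lists of unchanged simulated genes, camera called 0 in every comparison, but simulated genes vary independently, which favours the preset correlation.

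Alternatives were pseudocounts of 0.1 and 5, no filter, a stricter filter of 5 FPKM, TPM (each library rescaled to an equal sum), median-of-ratios scaling, quantile normalization, only the groups compared, library weights (limma array weights), the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry, a limma test of whether the members of a list move 1 way on balance. Chosen after seeing the data were the sham libraries of days 3 and 21 as controls of UIR day 1, and equal sums without the 100 most abundant genes. TPM moved the median log2 fold of all genes from 0.44 to 0.75 at day 3 and from 0.53 to 0.76 at day 21, and between sham days 1 and 3 from -0.12 to -0.23. Median-of-ratios scaling moved it to 0.03 at day 3 and 0.05 at day 21. Quantile normalization moved it to 0.01 at day 3 and -0.01 at day 21. List medians are therefore also given relative to the median of all genes.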

Results

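The mice were aged 11 weeks, 3 per group and day. UIR mice had the right renal pedicle clamped for 45 minutes, the left kidney intact, and the kidney sequenced is not named. FPKM sums per library ran from 424207 to 549490. In UIR kidneys the number of genes at 1 FPKM or more was 12375 ± 97 at day 1, 13372 ± 139 at day 3 and 14115 ± 63 at day 21 (SD, n = 3 each), against 12530 ± 50, 12135 ± 95 and 12141 ± 131 in sham kidneys. The 10 most abundant genes took 16.1% ± 0.6, 18.8% ± 0.8 and 18% ± 0.7 of the FPKM sum in sham kidneys at days 1, 3 and 21, and 14.4% ± 1.3, 7.2% ± 0.4 and 6.5% ± 0.5 in UIR kidneys (SD, n = 3 each). The first principal component held 61.2% of the variance and separated UIR from sham kidneys, least at day 1 and most at day 21. On the second, with 17.9%, sham day-1 kidneys lay apart from the later sham kidneys.

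**Figure D1:**
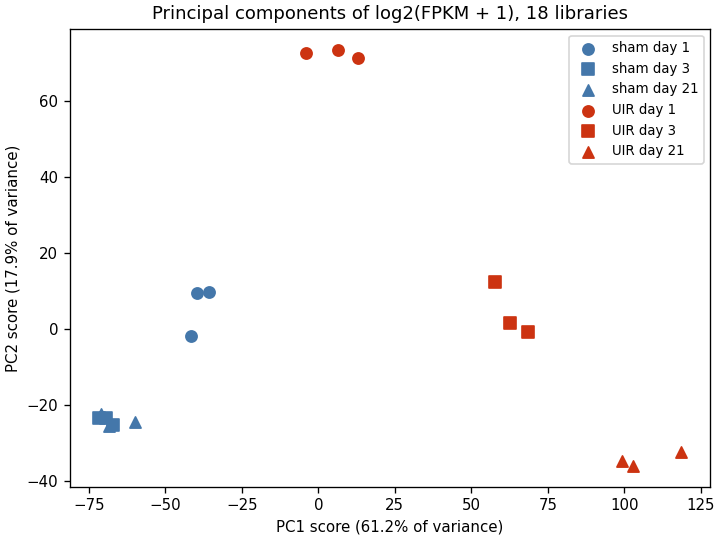
Each point is 1 of the 18 libraries, placed on the first (61.2% of variance) and second (17.9%) principal components of log2(FPKM + 1), with groups by color and shape. Sham libraries of days 3 and 21 lie together, sham day-1 libraries lie apart toward UIR day 1, and UIR libraries spread along the first component by day.

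The comparison at day 1 asks what clamping changed early after reperfusion. Transcripts of injured tubule cells, heat shock proteins and immediate early transcription factors rose. Transcripts for fatty acid oxidation and NAD synthesis fell. The single markers Mki67 of proliferation, Cd3e of T cells, Cd79a of B cells and Adgre1 of macrophages were not past the threshold. Krt20 (Entrez Gene 66809), a keratin of stressed epithelium, rose from 17.6 ± 10.8 to 1160 ± 195 FPKM (log2 fold 6.17 ± 0.39, limma adjusted p = 3.8e-09). Lcn2 (16819), the iron-binding injury marker NGAL, rose from 169 ± 59.6 to 2282 ± 760 FPKM (log2 fold 3.76 ± 0.38, limma adjusted p = 4.8e-07). Havcr1 (171283), the phosphatidylserine receptor KIM-1 of injured proximal tubules, rose from 30.9 ± 14.9 to 161 ± 127 FPKM (log2 fold 2.17 ± 0.56, limma adjusted p = 0.0035). Further large increases were in the inducible chaperones Hspa1a (5.95) and Hspa1b (5.30), the AP-1 subunit Fosl1 (5.42), the retinoic acid-induced receptor Gprc5a (5.28), the secreted neuropeptide precursor Vgf (5.04), the neutrophil chemokine Cxcl2 (4.79) and the cornified envelope protein Sprr2f (4.78), all as log2 folds at limma adjusted p of 3.3e-06 or lower. Cyp4a14 (13119), a fatty acid omega-hydroxylase, fell from 923 ± 210 to 9.0 ± 5.01 FPKM (log2 fold -6.67 ± 0.45, limma adjusted p = 7.2e-09). Other large decreases were the glutamine transporter Slc38a3 (-4.96), the omega-hydroxylase Cyp4a10 (-4.48), the endoplasmic reticulum shaping protein Reep6 (-4.27), the protease inhibitor Serpina1d (-4.21), the coumarin hydroxylase Cyp2a5 (-4.20) and the tyrosine-degrading enzyme Hpd (-4.13), at limma adjusted p of 6.1e-07 or lower.

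In all, 8770 of 14716 genes (59.6%) passed the threshold at day 1, 4187 higher and 4583 lower in UIR kidneys, of which 1026 rose and 1312 fell by at least 2-fold. All 3 UIR values lay on 1 side of the 3 sham values for 61.3% of genes, where chance gives 10%. Among the markers, the repair-associated transcription factor Sox9 rose (1.60), as did the cell cycle inhibitor Cdkn1a (2.68, from 54.5 ± 21.8 to 337 ± 70 FPKM), the adhesion molecule Vcam1 (0.61) and the matrix glycoprotein Fn1 (1.05). The nuclear receptor Hnf4a (-2.28, from 212 ± 16.1 to 44.1 ± 12.1 FPKM) and the mitochondrial coactivator Ppargc1a (-0.91) fell. Complement component C3 fell from 80.1 ± 12.6 to 8.60 ± 1.49 FPKM (log2 fold -3.08 ± 0.21, limma adjusted p = 1.0e-08). Against the later sham libraries, a control chosen after seeing the data, C3 was instead higher (0.83, limma adjusted p = 7.9e-04). Not past the threshold were the phosphate transporter Slc34a1 (log2 fold -0.45), the glucose transporter Slc5a2 (0.05), Umod of the thick ascending limb (0.36), the proliferation marker Mki67 (0.02), the monocyte chemokine Ccl2 (0.45), the macrophage marker Adgre1 (-0.44), Cd3e of T cells (-0.24), Cd79a of B cells (0.11), collagen Col1a1 (-0.98) and smooth muscle actin Acta2 (0.44), with the lowest limma adjusted p of these at 0.057.

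Of the 25 lists, 8 were called by camera at day 1, 4 up and 4 down. Of 28 tubular injury genes 24 rose and 2 fell, or 25 and 2 adjusted over the list alone (median log2 fold 2.26, 2.29 relative to all genes, camera adjusted p = 8.9e-10). They included Krt20, Sprr2f and the urokinase receptor Plaur (3.90). The fibrinogen chains Fga (-2.22) and Fgg (-2.08) were its 2 members that fell. Cytosolic heat shock genes rose in 10 of 12 cases, or 11 adjusted over the list alone (median log2 fold 1.71, 1.73 relative to all genes, camera adjusted p = 1.5e-04). Named members were the chaperones Hsp90aa1 (2.57) and Hspb1 (2.48). Of 18 immediate early genes 12 rose, also adjusted over the list alone (median log2 fold 1.49, 1.52 relative to all genes, camera adjusted p = 1.1e-04). These included the transcription factors Fosl1, Klf6 (3.39) and Fosb (2.56) and the phosphatase Dusp1 (2.62). Neutrophil genes rose in 11 of 14 cases, or 12 adjusted over the list alone (median log2 fold 1.22, 1.24 relative to all genes, camera adjusted p = 0.03). Among them were the decoy receptor Il1r2 (2.82) and the granule proteins Retnlg (2.55), Ngp (2.02) and S100a9 (1.95), while Ly6g (-1.17) and Lrg1 (-0.81) fell. The neutrophil call ended without sham day-1 replicate 2 (adjusted p = 0.081) or UIR day-1 replicates 1 (0.11) or 2 (0.082), and under the stricter filter (0.22) or a pseudocount of 5 (0.053).

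Fatty acid oxidation genes fell in 26 of 27 cases, also adjusted over the list alone (median log2 fold -1.25, -1.23 relative to all genes, camera adjusted p = 1.2e-11). They included the peroxisomal enzymes Acaa1b (-2.91) and Ehhadh (-2.57) and the mitochondrial isomerase Eci1 (-2.57). Of 11 genes of NAD biosynthesis from tryptophan 10 fell, also adjusted over the list alone (median log2 fold -1.43, -1.40 relative to all genes, camera adjusted p = 0.001). Named members were the dioxygenase Ido2 (-1.72), the hydroxylase Kmo (-1.62), the NAD synthetase Nadsyn1 (-1.57) and the formamidase Afmid (-1.48). Proximal tubule genes fell in 21 of 35 cases with none higher, also adjusted over the list alone (median log2 fold -1.04, -1.02 relative to all genes, camera adjusted p = 0.0047). These included the anion transporter Slc22a7 (-3.26), the gluconeogenic enzyme Pck1 (-2.83), the fatty acid transporter Slc27a2 (-2.32) and Hnf4a. Of 36 genes of the tricarboxylic acid cycle and respiratory chain 20 fell and 1 rose, also adjusted over the list alone (median log2 fold -0.30, -0.27 relative to all genes, camera adjusted p = 0.0041). Fh1 (-0.95), Idh2 (-0.93) and Suclg1 (-0.89) fell, and citrate synthase Cs (0.27) rose. Without UIR day-1 replicate 3 the proximal tubule list (median -0.71, adjusted p = 0.1) and the tricarboxylic acid cycle and respiratory chain list (median -0.20, adjusted p = 0.063) were no longer called.

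The adjusted p of these 8 lists with an estimated correlation ran from 0.35 to 0.8. Of the check lists, androgen-dependent kidney genes fell in 7 of 8 cases (median -1.46, camera adjusted p = 0.045). Among them were Cyp2d9 (-3.90), Cyp4a12b (-2.05), Cyp7b1 (-1.89) and Acsm3 (-1.71), while Odc1 rose (0.93). That call ended without sham day-1 replicate 1 (0.093), 2 (0.052) or 3 (0.076) or UIR day-1 replicate 3 (0.13), and with a pseudocount of 0.1 (0.099), without the filter (0.058), under the stricter filter (0.076), in TPM (0.06), with library weights (0.06) and with an estimated correlation (0.46). Of 5 adipose tissue genes 4 fell (median -1.35, camera adjusted p = 0.045), namely Aqp7 (-1.55), Plin1 (-1.46), Cidec (-1.35) and Plin4 (-1.23), and Car3 rose (1.69). The call ended without UIR day-1 replicate 3 (0.065), with a pseudocount of 0.1 (0.099), without the filter (0.01, 0.42), in TPM (0.055) and with an estimated correlation (0.31). The clock (median 0.42) and erythroid (median -0.46) lists were not called (camera adjusted p = 0.43 for both). The lists not called, with the lowest camera adjusted p at 0.098, were ATF4 and unfolded protein response (median 0.60, 10 of 21 higher and 3 lower), glycolysis (0.17), cell cycle (0.15), p53 target (0.25), extracellular matrix and myofibroblast (0.01), cytokine and chemokine (0.34), major histocompatibility complex class II presentation (-0.86, 7 of 9 lower), collecting duct (0.70, 10 of 18 higher and 7 lower), thick ascending limb and distal convoluted tubule (-0.37), podocyte (-0.06), endothelial cell (0.02), monocyte and macrophage (0.28), T cell and natural killer cell (-0.12), B cell and plasma cell (-0.18), interferon-stimulated (0.00), complement (-0.40) and NRF2 target (0.24).

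Sham kidneys of day 1 differed from the later sham kidneys in 4695 genes in the same direction against both, so day-1 folds depend on the control. Against the sham libraries of days 3 and 21, 10528 genes passed the threshold at day 1, of which 7361 were shared in the same direction and 266 in the opposite one. Against these Krt20 (9.50), Lcn2 (9.35) and Havcr1 (5.82) had larger log2 folds, Slc34a1 (-1.94), Umod (0.66), Ccl2 (1.00), Adgre1 (-0.48), Cd79a (-0.51), Col1a1 (-0.92) and Acta2 (0.82) passed the threshold, Cyp2a5 (-0.53) and Pck1 (-0.79) no longer did, and C3, Cidec (1.33) and Plin4 (0.47) turned to increases. The falls of Cyp4a14 (-2.54), Slc38a3 (-2.75), Cyp4a10 (-2.42) and Reep6 (-2.46) were smaller. Plin1 (0.01) and the adipose tissue list (0.01) were at no change, 4 further lists were called upward, namely p53 target (0.79), cytokine and chemokine (1.00), NRF2 target (0.93) and ATF4 and unfolded protein response (1.21), and all 8 lists stayed called in their direction, with tubular injury at 28 of 28 higher (median 3.76) and fatty acid oxidation at 22 of 27 lower (median -0.92).

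**Figure D2:**
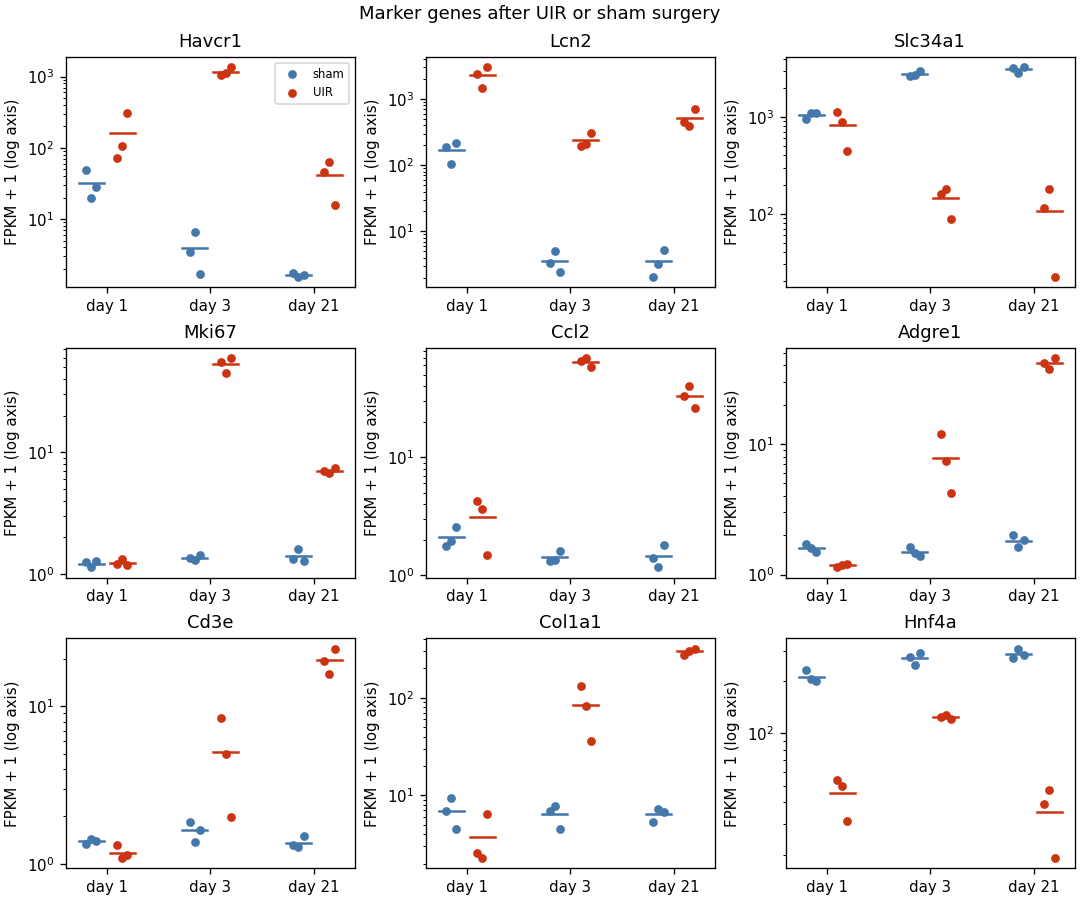
Panels show FPKM + 1 on a log axis for Havcr1, Lcn2, Slc34a1, Mki67, Ccl2, Adgre1, Cd3e, Col1a1 and Hnf4a in sham and UIR kidneys at days 1, 3 and 21, with points for the 3 libraries of a group and a line at the group mean. The means of Havcr1 and Lcn2 lie above those of sham at every day, and Mki67 is highest at day 3 (52.1 FPKM).

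The comparison at day 3 asks what followed the early change. Every cell cycle gene of the list rose, with macrophage, interferon-stimulated, cytokine and matrix transcripts. Transport and metabolic transcripts of the proximal tubule fell, with those of the respiratory chain. Havcr1 rose from 2.89 ± 2.46 to 1176 ± 152 FPKM (log2 fold 8.44 ± 0.56, limma adjusted p = 1.7e-09). Vcam1 (22329), a leukocyte adhesion molecule, rose from 2.37 ± 0.626 to 177 ± 9.21 FPKM (log2 fold 5.74 ± 0.13, limma adjusted p = 4.7e-14). Mki67 rose from 0.363 ± 0.0651 to 52.1 ± 7.53 FPKM (log2 fold 5.28 ± 0.11, limma adjusted p = 4.7e-14). Other large increases were in the calcium-binding protein S100a6 (6.32), Lcn2 (6.08, from 2.59 ± 1.35 to 236 ± 57.8 FPKM), the hyaluronan receptor Cd44 (5.70), the histone gene Hist1h2ao (5.52), Ccl2 (5.50) and the ribonucleotide reductase subunit Rrm2 (5.33), at limma adjusted p of 3.5e-09 or lower. Slc7a13 (74087), an aspartate and glutamate transporter of the proximal tubule, fell from 407 ± 51.7 to 0.453 ± 0.178 FPKM (log2 fold -8.13 ± 0.49, limma adjusted p = 5.0e-10). Kap (16483), the androgen-regulated kidney protein that was among the most abundant transcripts of sham kidneys, fell from 45804 ± 4734 to 523 ± 12.1 FPKM (log2 fold -6.44 ± 0.44, limma adjusted p = 2.1e-09). The methyltransferase Inmt (-7.44), the carboxylesterase Ces1f (-7.08), the cytochromes P450 Cyp2e1 (-6.69), Cyp2a4 (-6.65) and Cyp4a14 (-6.50) and the glycosyltransferase Ugt3a1 (-6.48) also fell, at limma adjusted p of 2.6e-09 or lower.

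At day 3, 11104 of 14716 genes (75.5%) passed the threshold, 8470 higher and 2634 lower, of which 3361 rose and 1149 fell by at least 2-fold, and 78.7% of genes were separated without overlap (10% by chance). The share of calls that were higher was 76.3% as deposited, 84.1% in TPM, and 51.2% after both median-of-ratios scaling and quantile normalization, each of which centres all genes. Further markers that rose were Krt20 (5.05), Sox9 (4.34), Cdkn1a (3.93), C3 (4.31, from 5.63 ± 1.37 to 134 ± 49.9 FPKM), Adgre1 (2.26), Cd3e (1.43), Col1a1 (3.56, from 5.43 ± 1.70 to 83.1 ± 48.5 FPKM), Fn1 (3.25) and Acta2 (2.05). Slc34a1 (-4.34, from 2783 ± 164 to 143 ± 49.2 FPKM), Slc5a2 (-2.78) and Hnf4a (-1.13) fell, and Ppargc1a (-0.40) was not past the threshold (limma adjusted p = 0.051). Umod (-0.49, limma adjusted p = 0.013) fell. This call ended without sham day-3 replicate 2 (-0.37, 0.071) or UIR day-3 replicate 3 (-0.37, 0.075), in TPM (-0.21, 0.24) and after quantile normalization (-0.12, 0.52). Cd79a (-0.37, limma adjusted p = 0.018) fell. That call ended without sham day-3 replicate 2 (-0.29, 0.083) or UIR day-3 replicates 2 (-0.30, 0.081) or 3 (-0.33, 0.061), and in TPM (-0.40, 0.06).

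Of the 25 lists, 14 were called at day 3, 7 up and 7 down. All 36 cell cycle genes rose, also adjusted over the list alone (median log2 fold 4.06, 3.62 relative to all genes, camera adjusted p = 1.9e-15). They included Rrm2, Mki67, the mitotic cyclin Ccnb2 (5.13) and the anaphase activator Cdc20 (5.12). Tubular injury genes rose in 24 of 28 cases, also adjusted over the list alone, where 1 fell (median log2 fold 3.94, 3.50 relative to all genes, camera adjusted p = 9.8e-06). Of 36 extracellular matrix and myofibroblast genes 35 rose, also adjusted over the list alone (median log2 fold 2.05, 1.61 relative to all genes, camera adjusted p = 2.0e-04). Named members were the metalloproteinase inhibitor Timp1 (4.44), tenascin Tnc (3.63) and Col1a1. Monocyte and macrophage genes rose in 23 of 24 cases and fell in 1, also adjusted over the list alone (median log2 fold 2.43, 1.99 relative to all genes, camera adjusted p = 0.001). These included lysozyme Lyz2 (3.97), the endotoxin receptor Cd14 (3.41), Gpnmb of lipid-laden macrophages (3.21) and complement C1qb (3.01). Of 24 interferon-stimulated genes 21 rose, also adjusted over the list alone (median log2 fold 1.29, 0.85 relative to all genes, camera adjusted p = 0.0097). Among them were Ifit2 (2.35), the GTPase Gbp2 (2.23), the RNA sensor Ddx58 (2.22) and Oasl2 (2.11). Of 20 p53 targets 16 rose and 1 fell, or 17 and 1 adjusted over the list alone (median log2 fold 1.05, 0.61 relative to all genes, camera adjusted p = 0.013). They included Psrc1 (3.48), Phlda3 (2.98), the stress cytokine Gdf15 (2.62) and Cdkn1a. Cytokine and chemokine genes rose in 16 of 23 cases, also adjusted over the list alone (median log2 fold 1.90, 1.46 relative to all genes, camera adjusted p = 0.028). Named members were the neutrophil chemokines Cxcl1 (4.83) and Cxcl2 (3.90), the macrophage growth factor Csf1 (3.77) and Ccl2. The call ended in TPM (adjusted p = 0.07) and with a pseudocount of 5 (0.083).

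Proximal tubule genes fell in 33 of 35 cases and rose in 1, also adjusted over the list alone (median log2 fold -2.78, -3.22 relative to all genes, camera adjusted p = 7.9e-19). These included the anion transporters Slc22a8 (-6.26) and Slc22a7 (-5.86), the inositol oxygenase Miox (-5.71) and Kap, while the amino acid transporter Slc7a8 rose (0.47). Of 36 tricarboxylic acid cycle and respiratory chain genes 35 fell, also adjusted over the list alone (median log2 fold -1.17, -1.61 relative to all genes, camera adjusted p = 4.2e-23). Among them were Sdhb (-1.90), Cox7a2 (-1.66), Cox4i1 (-1.49) and Ndufb8 (-1.45). Fatty acid oxidation genes fell in 25 of 27 cases, or 26 adjusted over the list alone (median log2 fold -1.45, -1.88 relative to all genes, camera adjusted p = 7.9e-19). They included Ehhadh (-4.09), Acaa1b (-3.58) and Acadm (-2.53). All 11 genes of NAD biosynthesis from tryptophan fell, also adjusted over the list alone (median log2 fold -1.11, -1.55 relative to all genes, camera adjusted p = 3.7e-08). Among them were Haao (-4.90), Kmo (-4.33), Afmid (-2.45) and, on a branch away from NAD, Acmsd (-3.85). Of 19 thick ascending limb and distal convoluted tubule genes 10 fell and 4 rose, also adjusted over the list alone (median log2 fold -0.49, -0.93 relative to all genes, camera adjusted p = 3.1e-04). These included parvalbumin Pvalb (-5.25), the growth factor Egf (-4.04), calbindin Calb1 (-3.10) and claudin Cldn10 (-1.56). This call ended after quantile normalization (0.053).

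NRF2 targets, genes of the oxidative stress response, were mixed, 10 of 17 lower and 6 higher, also adjusted over the list alone (median log2 fold -0.36, -0.79 relative to all genes, camera adjusted p = 0.0097). Osgin1 (-2.13), Gstm1 (-1.97), Me1 (-1.85) and Gsta2 (-1.80) fell, Gsta1 (2.89), Hmox1 (1.46) and G6pdx (1.24) rose, and the call ended after quantile normalization (-0.05, 0.77). Collecting duct genes were also mixed, 6 of 18 higher and 6 lower, also adjusted over the list alone (median log2 fold -0.21, -0.65 relative to all genes, camera adjusted p = 0.04). The water channels Aqp2 (-1.10) and Aqp3 (-1.02), the vasopressin receptor Avpr2 (-0.80) and Tmem213 (-0.63) fell, while Fxyd4 (0.95), Foxi1 (0.79) and Krt7 (0.65) rose. In TPM the collecting duct median turned to 0.07 (0.063), and its call also ended without sham day-3 replicate 1 (-0.15, 0.1) or UIR day-3 replicate 1 (-0.21, 0.051), under the stricter filter (0.051) and after quantile normalization (-0.34, 0.41). With an estimated correlation, the adjusted p of the 14 lists ran from 0.086 for fatty acid oxidation and NAD biosynthesis to 0.59 for interferon-stimulated genes.

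All 8 androgen-dependent kidney genes fell (median -4.55, camera adjusted p = 3.0e-08, adjusted p = 0.03 with an estimated correlation). Among them were Cyp4a12a (-5.88), Cyp2d9 (-5.72), Acsm3 (-5.66) and Slco1a1 (-5.45). Of 7 erythroid genes 5 fell and 1 rose (median -3.28, camera adjusted p = 0.006). They included the hemoglobin genes Hbb-bt (-3.46), Hbb-bs (-3.33), Hba-a1 (-3.33, from 532 ± 459 to 41.1 ± 1.96 FPKM) and Hba-a2 (-3.28). That call ended after median-of-ratios scaling (0.072), quantile normalization (0.063) and with an estimated correlation (0.2). Clock genes were mixed, 7 of 16 lower and 4 higher (median -0.20, camera adjusted p = 0.03), and the transcription factors Hlf (-3.27), Dbp (-2.25) and Tef (-1.59) fell. In sham day-3 replicate 2 clock genes stood apart from its group, with Dbp at 6.29 against 74.04 and 55.9 FPKM. Without it the list median was -0.43 (camera adjusted p = 0.011), Dbp -3.31 and Ciart -1.74. The median was -0.10 without replicate 1 (0.035) and -0.06 without replicate 3 (0.044). Dbp lost its call where only the groups compared were fitted (0.053). The clock list call ended after median-of-ratios scaling (-0.68, 0.17), quantile normalization (-0.70, 0.078), without the filter (0.066) and with an estimated correlation (0.17), and in TPM the list median was 0.06. Ciart, a clock repressor, fell (-1.11, limma adjusted p = 0.033). The call ended without sham day-3 replicate 1 (-0.76, 0.16) or 3 (-0.82, 0.14) or UIR day-3 replicate 1 (-1.13, 0.06), 2 (-1.09, 0.068) or 3 (-1.09, 0.066), with a pseudocount of 5 (0.072), without the filter (0.053), in TPM (0.063) and where only the groups compared were fitted (0.081). Adipose tissue genes were not called (median -0.03, camera adjusted p = 0.074). Immediate early genes rose in 15 of 18 cases (median 1.77, camera adjusted p = 0.065), T cell and natural killer cell genes in 20 of 24, or 22 adjusted over the list alone (median 1.04, camera adjusted p = 0.3), and class II presentation genes in 8 of 9 (median 1.37, camera adjusted p = 0.36), without a call against all other genes. The medians of the other lists not called were 0.80 for podocyte, 0.44 for endothelial cell, 0.49 for glycolysis, 0.49 for neutrophil, -0.03 for B cell and plasma cell, 1.22 for complement, 0.64 for ATF4 and unfolded protein response and 0.57 for heat shock genes, with a median of 0.44 over all genes.

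The comparison at day 21 asks what remained 3 weeks after the surgery. Transcripts of macrophages, T cells, B cells, antigen presentation, interferon response and matrix were high. All 35 proximal tubule genes of the list were low, as were all genes of the respiratory chain list. Lyz2 (17105), lysozyme of macrophages and neutrophils, rose from 10.8 ± 2.24 to 2037 ± 389 FPKM (log2 fold 7.43 ± 0.37, limma adjusted p = 5.5e-11). C3 (12266) rose from 3.43 ± 0.601 to 214 ± 13.1 FPKM (log2 fold 5.61 ± 0.21, limma adjusted p = 6.0e-12). Col1a1 (12842), the fibrillar collagen chain, rose from 5.47 ± 1.01 to 297 ± 21.8 FPKM (log2 fold 5.53 ± 0.42, limma adjusted p = 5.2e-09). Large increases were also in Lcn2 (7.24, from 2.53 ± 1.60 to 514 ± 165 FPKM), Gpnmb (6.82), Lyz1 (6.37), the resistin-like cytokine Retnla (6.08), the lysosomal protease Ctss (5.97), the chemokine Ccl8 (5.92) and the macrophage elastase Mmp12 (5.87), at limma adjusted p of 7.6e-11 or lower. Miox (56727) fell from 1871 ± 205 to 26.8 ± 21.0 FPKM (log2 fold -6.57 ± 0.59, limma adjusted p = 3.7e-08). Slc34a1 (20505) fell from 3115 ± 224 to 105 ± 80.1 FPKM (log2 fold -5.33 ± 0.54, limma adjusted p = 1.4e-07). The steroid hydroxylase Cyp2a4 (-6.83), the acyl-CoA synthetase Acsm3 (-6.56), Slc7a13 (-6.51), the zinc-binding glycoprotein Azgp1 (-6.21), the omega-hydroxylase Cyp4a12a (-6.03), Slc22a8 (-5.94) and Inmt (-5.83) were the other largest decreases, at limma adjusted p of 3.8e-09 or lower.

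At day 21, 11885 of 14716 genes (80.8%) passed the threshold, 8934 higher and 2951 lower, of which 4336 rose and 1407 fell by at least 2-fold, and 84.3% were separated without overlap (10% by chance). The share of calls that were higher was 75.2% as deposited, 80.2% in TPM, 52.3% after median-of-ratios scaling and 49.2% after quantile normalization. All 20 markers passed the threshold. Those that rose included Havcr1 (4.44, from 0.653 ± 0.0902 to 40.7 ± 23.7 FPKM), Krt20 (2.36), Sox9 (3.29), Vcam1 (5.22), Cdkn1a (3.84), Mki67 (2.33), Ccl2 (4.51), Adgre1 (4.52, from 0.817 ± 0.190 to 40.6 ± 3.85 FPKM), Cd3e (3.84, from 0.357 ± 0.117 to 18.6 ± 3.57 FPKM), Fn1 (4.5) and Acta2 (3.06). Cd79a rose (1.15). This call ended after quantile normalization (0.23, limma adjusted p = 0.13). Hnf4a (-3.13, from 287 ± 18.4 to 34.1 ± 14.4 FPKM), Slc5a2 (-4.26), Umod (-0.66) and Ppargc1a (-0.62) fell.

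Of the 25 lists, 20 were called at day 21, 12 up and 8 down. All 36 extracellular matrix and myofibroblast genes rose, also adjusted over the list alone (median log2 fold 3.66, 3.13 relative to all genes, camera adjusted p = 2.6e-07). Named members were Col1a1, Timp1 (5.50), collagen Col3a1 (5.36) and the gelatinase Mmp2 (5.06). Monocyte and macrophage genes rose in 23 of 24 cases, Lyz2 and Gpnmb among them, also adjusted over the list alone (median log2 fold 4.33, 3.79 relative to all genes, camera adjusted p = 1.8e-05). All 24 T cell and natural killer cell genes rose, also adjusted over the list alone (median log2 fold 2.95, 2.42 relative to all genes, camera adjusted p = 1.0e-04). These included Cd3g (4.18), Cd4 (3.84) and Cd2 (3.77). All 9 class II presentation genes rose, also adjusted over the list alone (median log2 fold 4.07, 3.54 relative to all genes, camera adjusted p = 0.0054). Among them were H2-Eb1 (4.83), H2-Aa (4.81) and the invariant chain Cd74 (4.74, from 178 ± 15.8 to 4817 ± 961 FPKM). The 9 B cell and plasma cell genes all rose, also adjusted over the list alone (median log2 fold 1.81, 1.28 relative to all genes, camera adjusted p = 0.017). They included the joining chain Jchain (3.67), Spib (2.71), H2-Ob (2.39) and Cd22 (2.16). That call ended without UIR day-21 replicate 1 (1.47, 0.072) or 3 (1.44, 0.079). Every interferon-stimulated gene of 24 rose, also adjusted over the list alone (median log2 fold 2.57, 2.04 relative to all genes, camera adjusted p = 4.0e-05). Named members were Oasl2 (3.67), the nucleic acid sensor Zbp1 (3.48), Gbp2 (3.40) and Rtp4 (3.34). Every cytokine and chemokine gene of 23 rose, also adjusted over the list alone (median log2 fold 3.20, 2.66 relative to all genes, camera adjusted p = 1.2e-04). These included Cxcl5 (4.68) and Ccl9 (4.49).

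All 36 cell cycle genes rose at day 21, also adjusted over the list alone (median log2 fold 1.5, 0.97 relative to all genes, camera adjusted p = 2.4e-05). Among them were the licensing factor Mcm3 (2.49), topoisomerase Top2a (2.41) and survivin Birc5 (2.18). Tubular injury genes rose in 23 of 28 cases, also adjusted over the list alone (median log2 fold 3.37, 2.83 relative to all genes, camera adjusted p = 0.0014). They included keratin Krt19 (5.50) and S100a6 (4.68), while Fga (-1.47) and Fgg (-1.13) fell. Podocyte genes rose in 15 of 16 cases, also adjusted over the list alone (median log2 fold 1.49, 0.96 relative to all genes, camera adjusted p = 0.036). Named members were Tcf21 (3.23), Kirrel (2.93) and Synpo (2.14). Endothelial cell genes rose in 19 of 20 cases, also adjusted over the list alone (median log2 fold 1.34, 0.81 relative to all genes, camera adjusted p = 0.035). These included Cd34 (2.33), Cldn5 (1.66), Pecam1 (1.59) and Esam (1.57). The call ended without sham day-21 replicate 1 (1.30, 0.055). Of 18 immediate early genes 16 rose, also adjusted over the list alone (median log2 fold 2.10, 1.57 relative to all genes, camera adjusted p = 0.035). Among them were the transcription factors Egr2 (3.73), Fosl2 (3.42), Egr1 (3.26) and Fos (3.11). This call ended without sham day-21 replicate 1 (2.03, 0.053) or UIR day-21 replicate 3 (2.10, 0.058).

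All 35 proximal tubule genes fell, also adjusted over the list alone (median log2 fold -4.53, -5.07 relative to all genes, camera adjusted p = 1.5e-22), from Slc7a8 (-0.64) to Miox (-6.57), with Kap (-5.80) and the anion transporter Slc22a6 (-5.73). All 36 tricarboxylic acid cycle and respiratory chain genes fell, also adjusted over the list alone (median log2 fold -1.53, -2.06 relative to all genes, camera adjusted p = 1.8e-25). They included Uqcrfs1 (-2.13), Sdhb (-2.00) and Suclg1 (-1.90). All 27 fatty acid oxidation genes fell, also adjusted over the list alone (median log2 fold -1.71, -2.25 relative to all genes, camera adjusted p = 4.7e-19). Named members were Ehhadh (-4.66), Acaa1b (-4.49) and their nuclear receptor Ppara (-2.87). Of 11 genes of NAD biosynthesis from tryptophan 10 fell, also adjusted over the list alone (median log2 fold -2.04, -2.57 relative to all genes, camera adjusted p = 7.9e-08). These included Haao (-4.09), Kmo (-3.07), Afmid (-2.59) and, on a branch away from NAD, Acmsd (-4.45). NRF2 targets rose in 2 cases and fell in 10 of 17, also adjusted over the list alone (median log2 fold -0.99, -1.52 relative to all genes, camera adjusted p = 3.9e-06). Among them were Me1 (-4.07), Gsta2 (-3.99), Osgin1 (-2.79) and the quinone reductase Nqo1 (-2.77).

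Glycolysis genes moved both ways, 9 of 18 lower and 7 higher, also adjusted over the list alone (median log2 fold -0.16, -0.70 relative to all genes, camera adjusted p = 0.024). Their mean log2 fold, 0.19, had the opposite sign to the median. Gapdh (-1.54), Pgk1 (-1.52), Tpi1 (-1.41) and Ldha (-1.01) fell while hexokinase Hk2 (2.72), the lactate transporter Slc16a3 (2.07) and the kinase Pfkfb3 (1.95) rose. In TPM the glycolysis median was 0.03, and its call ended after median-of-ratios scaling (-0.74, 0.097) and quantile normalization (-0.25, 0.67). Thick ascending limb and distal convoluted tubule genes fell in 9 of 19 cases and rose in 4, or 8 and 4 adjusted over the list alone (median log2 fold -0.32, -0.85 relative to all genes, camera adjusted p = 0.0014). They included Calb1 (-5.22), Egf (-4.77), Pvalb (-4.61) and the sodium chloride cotransporter Slc12a3 (-3.01). That call ended after quantile normalization (-0.51, 0.16). Collecting duct genes rose in 5 cases and fell in 7 of 18, also adjusted over the list alone (median log2 fold -0.06, -0.59 relative to all genes, camera adjusted p = 0.034). Named members were Aqp2 (-3.51), Aqp3 (-2.30), the anion exchangers Slc26a4 (-1.54) and Slc4a1 (-1.47). The collecting duct median was 0.13 in TPM and 0.03 without UIR day-21 replicate 3 (0.061), and its call ended under the stricter filter (0.061), median-of-ratios scaling (-0.64, 0.056) and quantile normalization (-0.05, 0.57). With an estimated correlation, the adjusted p of the 20 lists ran from 0.063 for fatty acid oxidation, NAD biosynthesis and NRF2 targets to 0.59 for endothelial cell genes.

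All 8 androgen-dependent kidney genes stayed low at day 21 (median -4.24, camera adjusted p = 1.1e-07, adjusted p = 0.037 with an estimated correlation). These included Slco1a1 (-5.55) and Cyp2d9 (-4.93). The clock (median 0.22), erythroid (-0.12) and adipose tissue (0.01) lists were not called (lowest camera adjusted p = 0.18). Complement genes rose in 10 of 13 cases and fell in 1 without a call (median 3.29, camera adjusted p = 0.06), and p53 targets rose in 16 of 20 cases and fell in 3 (median 0.98, camera adjusted p = 0.26). Neutrophil genes rose in 10 of 14 cases and fell in 1 (median 1.46, camera adjusted p = 0.38), ATF4 and unfolded protein response genes rose in 12 of 21 and fell in 1 (median 0.51, camera adjusted p = 0.81), and heat shock genes rose in 3 of 12 and fell in 5 (median 0.00, camera adjusted p = 0.12).

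**Figure D3:**
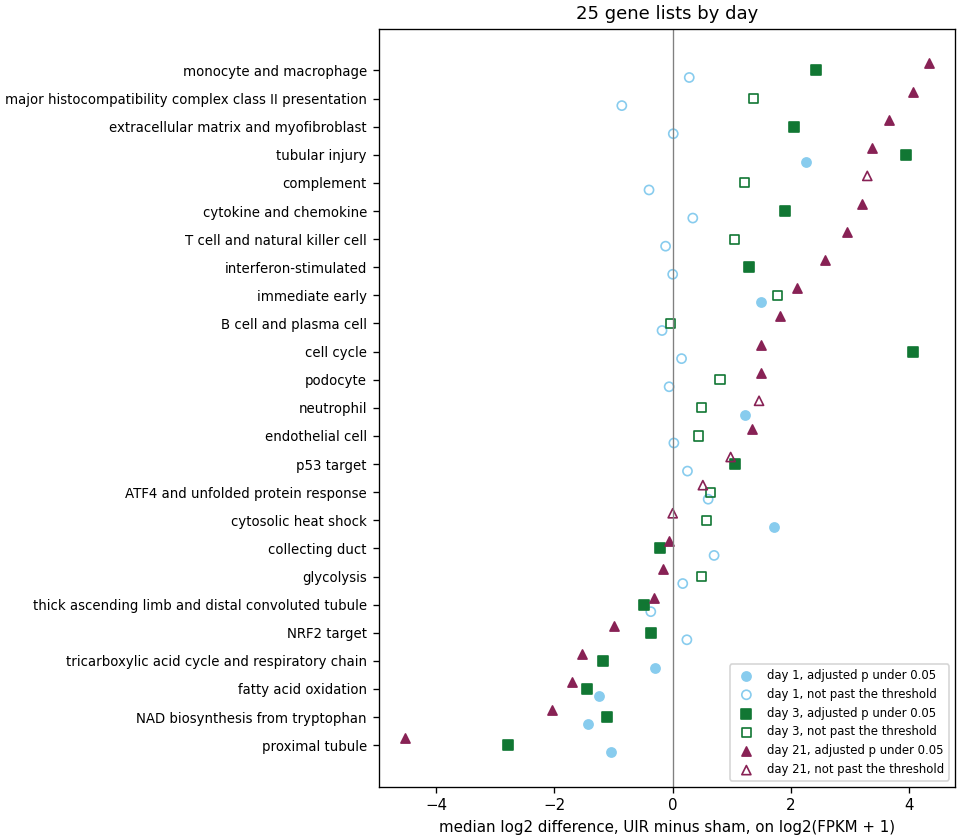
For each of the 25 lists, points give the median log2 fold of UIR against sham kidneys at days 1, 3 and 21 on the horizontal axis, filled where the camera adjusted p was under 0.05. Tubular injury lies at 2.26, 3.94 and 3.37 and the proximal tubule at -1.04, -2.78 and -4.53.

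How the response to clamping changed with time was tested as the difference between the effects of a pair of days. From day 1 to day 3, cell division, macrophage and interferon transcripts gained and heat shock, proximal tubule and respiratory chain transcripts lost. From day 3 to day 21, cell division receded while lymphocyte, antigen presentation and matrix transcripts gained. Between days 1 and 3 the effect differed for 9253 genes, 7377 toward higher, between days 3 and 21 for 6800, 3834 toward higher, and between days 1 and 21 for 10365, 7967 toward higher. The share toward higher was 79.7%, 56.4% and 76.9% as deposited, against 88.5%, 48.9% and 83.4% in TPM, 48.3%, 51.5% and 49.3% after median-of-ratios scaling and 50.1%, 46.0% and 46.5% after quantile normalization. Genes higher at all 3 days numbered 3049 and genes lower at all 3 days 1433. Those past the threshold in the same direction at days 1 and 3 numbered 3439 higher (2410 for independent lists) and 1726 lower (820), with 1644 in opposite directions. At days 3 and 21, 7255 were higher (5142) and 2114 lower (528) at both, with 298 opposite, and at days 1 and 21, 3327 (2542) and 1843 (919), with 1961 opposite.

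From day 1 to day 3 the largest gains of effect were in C3 (difference of log2 folds 7.39 ± 0.30, limma adjusted p = 5.7e-11), Havcr1 (6.27), the diamine oxidase Aoc1 (6.00) and the pseudogene Rpl14-ps1 (5.66). Hist1h2ao, at the same rank, was listed at 0 in all 3 UIR day-1 libraries and so has no fold to compare. The largest losses were in Slc7a13 (-7.56), Inmt (-6.66), Ces1f (-6.31), the steroid dehydrogenase Akr1c21 (-6.08) and Pvalb (-6.02). Of the 20 markers 18 differed, upward, besides C3 and Havcr1, for Vcam1 (5.13), Mki67 (5.25), Ccl2 (5.05), Col1a1 (4.54), Sox9 (2.74), Adgre1 (2.71), Lcn2 (2.32), Fn1 (2.2), Cd3e (1.68), Acta2 (1.61), Cdkn1a (1.25) and Hnf4a (1.15), and downward for Slc34a1 (-3.89), Slc5a2 (-2.83), Umod (-0.85) and Cd79a (-0.48). Cd79a (limma adjusted p = 0.034) lost its call without sham day-1 replicate 2 (0.071) or 3 (0.072), sham day-3 replicate 2 (0.088), UIR day-1 replicate 1 (0.053) or 2 (0.054), or UIR day-3 replicate 2 (0.09) or 3 (0.073), with a pseudocount of 5 (0.091) and in TPM (0.057). Krt20 (-1.13) and Ppargc1a (0.51) were not past the threshold. Of the lists 13 were called, 4 up and 9 down, led by cell cycle (median 3.66, camera adjusted p = 5.7e-20) and, downward, the tricarboxylic acid cycle and respiratory chain (median -0.75, camera adjusted p = 2.0e-20), the proximal tubule (median -2.05, camera adjusted p = 3.3e-14) and heat shock (median -1.75, camera adjusted p = 8.3e-05). Against the later sham libraries as day-1 control, the gains of C3 (3.48) and Havcr1 (2.62) were below that of Vcam1 (5.03), the losses of Slc7a13 (-4.69), Pvalb (-3.96) and Slc34a1 (-2.40) were smaller and Krt20 (-4.45) passed the threshold. Under it the differences of Lcn2 (-3.27) and Cdkn1a (-2.2) and the tubular injury list (median -0.79 in place of 1.16) turned, Sox9 (0.09) was no longer past the threshold, and Cd79a was 0.14. Calls also ended for Cdkn1a with a pseudocount of 5 (0.50, 0.19) and after median-of-ratios scaling (0.74, 0.12), for Hnf4a after that scaling (0.58, 0.18), and for Umod (-0.39, 0.17) and Cd3e (1.08, 0.06) after quantile normalization.

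From day 3 to day 21 the effect gained most in Retnla (6.06 ± 0.19), Mmp12 (5.50 ± 0.18), Ccl8 (5.00), the eosinophil-associated ribonuclease Ear2 (4.93) and matrilysin Mmp7 (4.29). It lost most in the vitamin D hydroxylase Cyp24a1 (-5.24), at 17.0, 101 and 4.23 FPKM in UIR kidneys of days 1, 3 and 21, the serine synthesis enzyme Phgdh (-4.17), at 13.8, 150 and 13.2 FPKM, Rrm2 (-4.04), Havcr1 (-4.00) and Cdc20 (-3.70). Of the markers 12 differed, upward for Cd3e (2.40), Adgre1 (2.26), Col1a1 (1.98), Cd79a (1.52), C3 (1.29), Fn1 (1.24) and Acta2 (1.00), and downward for Havcr1, Mki67 (-2.94), Krt20 (-2.69), Hnf4a (-2.00) and Vcam1 (-0.52). Vcam1 (limma adjusted p = 0.028) lost its call without sham day-3 replicate 1 (0.067) or 3 (0.07), sham day-21 replicate 2 (0.076), UIR day-3 replicate 1 (0.059) or 3 (0.054), or UIR day-21 replicate 3 (0.059), with a pseudocount of 0.1 (0.14) and after quantile normalization (0.072). Acta2 lost its call without sham day-3 replicate 2 (0.77, 0.058). Not past the threshold were Lcn2 (1.16), Sox9 (-1.05), Ccl2 (-0.99), Slc34a1 (-0.99), Slc5a2 (-1.48), Umod (-0.17), Ppargc1a (-0.22) and Cdkn1a (-0.09). Of the lists 18 were called, 10 up and 8 down, with all 36 cell cycle genes down (median -2.48, camera adjusted p = 1.6e-31) and T cell and natural killer cell (median 1.96, camera adjusted p = 2.8e-08), extracellular matrix and myofibroblast (median 1.54, camera adjusted p = 4.2e-08), monocyte and macrophage (median 2.10, camera adjusted p = 1.0e-07), B cell and plasma cell (median 1.77, camera adjusted p = 5.0e-06) and class II presentation genes (median 3.18, camera adjusted p = 1.4e-04) up. The tubular injury list fell back (median -0.72, camera adjusted p = 0.016). The call ended under the stricter filter (0.074), after quantile normalization (-0.97, 0.1) and with fry (0.053).

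Between days 1 and 21 the effect gained most in C3 (8.68 ± 0.30, limma adjusted p = 3.2e-11), the protease inhibitor Serpina1b (7.68), complement C1qa (6.66), Lyz2 (6.63) and Col1a1 (6.52), and lost most in Miox (-6.64), the steroid dehydrogenase Hsd3b2 (-6.24), Slc7a13 (-5.94), the membrane protein Fam151a (-5.59) and Hspa1a (-5.51). Of the markers 19 differed, all but Ppargc1a (0.30). The changes were upward, besides C3 and Col1a1, for Adgre1 (4.96), Vcam1 (4.61), Cd3e (4.08), Ccl2 (4.06), Lcn2 (3.48), Fn1 (3.45), Acta2 (2.62), Mki67 (2.31), Havcr1 (2.28), Sox9 (1.69), Cdkn1a (1.16) and Cd79a (1.04), and downward for Slc34a1 (-4.88), Slc5a2 (-4.30), Krt20 (-3.81), Umod (-1.02) and Hnf4a (-0.86). Havcr1 (limma adjusted p = 0.018) lost its call without sham day-1 replicate 1 (1.92, 0.051), UIR day-1 replicate 1 (1.84, 0.054) or UIR day-21 replicate 2 (1.88, 0.053). Hnf4a (limma adjusted p = 0.039) lost it without sham day-1 replicate 2 (0.067) or 3 (0.07), sham day-21 replicate 2 (0.073) or 3 (0.059), UIR day-1 replicate 1 (0.098) or 2 (0.085), or UIR day-21 replicate 3 (-0.47, 0.087), and also without the filter (0.056), in TPM (-0.68, 0.11), after quantile normalization (-0.88, 0.063), where only the groups compared were fitted (0.079) and with the later sham libraries as day-1 control (-0.46, 0.15). Against the later sham libraries as day-1 control, Havcr1 (-1.38), Lcn2 (-2.11), Sox9 (-0.96) and Cdkn1a (-2.29) turned. C3 (4.78) was then below Lyz2 (6.52), the losses of Hsd3b2 (-1.91), Slc7a13 (-3.08) and Fam151a (-3.33) were smaller, and the loss of Krt20 (-7.14) and the gain of Cd79a (1.66) were larger. With a pseudocount of 5 Havcr1 (0.82, 0.28), Sox9 (0.44, 0.19) and Cdkn1a (0.50, 0.17) lost their calls, as did Havcr1 (1.80, 0.056) and Cdkn1a (0.58, 0.19) after median-of-ratios scaling and Cd79a (0.08, 0.74) after quantile normalization. Of the lists 19 were called, 10 up and 9 down. NRF2 targets (median -1.88, camera adjusted p = 1.5e-08, 13 of 17 down and 3 up) were the 1 list also called with an estimated correlation (adjusted p = 0.041 with an estimated correlation).

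The sham groups give the background over time in kidneys that were not clamped. Sham kidneys of day 1 carried more tubular injury, immediate early, p53 and fatty acid oxidation transcripts than those of days 3 and 21, and less of the proximal tubule and the respiratory chain. Between sham days 3 and 21 the count of genes was 5, but 1756 with library weights and 418 without sham day-3 replicate 3. Between sham days 1 and 3, 6258 genes passed the threshold, 1881 higher and 4377 lower at day 3, and between sham days 1 and 21, 5804 did, 1806 higher and 3998 lower at day 21. Genes separated without overlap made up 53.3% and 54.1% (10% by chance). The share that was higher at the later day was 30.1% and 31.1% as deposited, 19.8% and 28.2% in TPM, 51.5% and 51.6% after median-of-ratios scaling and 51.9% and 52.3% after quantile normalization. Called in both comparisons were 3328 genes lower in the later groups (1189 for independent lists) and 1367 higher (231). Both share the sham day-1 libraries, so part of the excess may come from them (correlation across genes 0.91, simulated without effect 0.50).

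The fibrinogen chain Fgg fell from 328 ± 147 FPKM at sham day 1 to 3.28 ± 0.439 at day 3 and 5.81 ± 0.975 at day 21 (log2 difference -6.17 ± 0.46 to day 3, limma adjusted p = 8.1e-08). Lcn2 was 169 ± 59.6, 2.59 ± 1.35 and 2.53 ± 1.60 FPKM at sham days 1, 3 and 21. The pyruvate dehydrogenase kinase Pdk4 (-5.17) and the fibrinogen chains Fgb (-5.16) and Fga (-5.04) also fell to day 3, and to day 21 large decreases were in Cyp4a14 (-5.83), Lcn2 (-5.62), Pdk4 (-5.56) and Fgg (-5.51). Rises were largest in the steroid dehydrogenases Hsd3b2 (4.28 to day 3 and 4.39 to day 21) and Hsd3b4 (3.27 and 2.96), the hydroxyacid oxidase Hao2 (3.26 and 3.18), Acmsd (3.15 and 3.38) and the creatine synthesis enzyme Gatm (3.06 and 3.52). Of the markers, Lcn2, Havcr1 (-3.14 and -4.17), Krt20 (-3.54 and -3.10), Sox9 (-2.59 and -2.71), Cdkn1a (-3.56 and -3.34) and C3 (-3.62 and -4.19) were lower at both later days, and Cd79a was higher (0.63 and 0.61).

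Slc34a1 was higher at the later sham days (1.41, limma adjusted p = 0.047, and 1.57, limma adjusted p = 0.03), but both calls ended whichever library was left out, with adjusted p from 0.081 without sham day-1 replicate 2 to 0.11 without sham day-1 replicate 1 for day 3, and from 0.055 without sham day-21 replicate 2 to 0.083 without sham day-1 replicate 1 for day 21. Without sham day-1 replicate 3 they were 0.087 and 0.063, without sham day-3 replicates 1, 2 or 3 the first was 0.087, 0.087 and 0.1, and without sham day-21 replicates 1 or 3 the second was 0.073 and 0.075. Both calls also ended without the filter (0.078 and 0.052) and after quantile normalization (0.15 and 0.1), and the first in TPM (0.064) and with equal sums without the 100 most abundant genes (0.052). Umod was lower at sham day 21 (-0.48, limma adjusted p = 0.03). This call ended without sham day-1 replicate 2 (0.086) or 3 (0.065) or sham day-21 replicate 2 (0.1) or 3 (0.058), without the filter (0.054) and after median-of-ratios scaling (-0.33, 0.16). Umod at sham day 3 and the other markers were not past the threshold. Of the lists, 11 were called between sham days 1 and 3, 5 up and 6 down, and 10 between sham days 1 and 21, 3 up and 7 down. At day 3, 20 of 28 tubular injury genes were lower (median -1.56, camera adjusted p = 4.0e-07), 13 of 18 immediate early genes (median -1.77, camera adjusted p = 2.9e-04), 16 of 20 p53 targets (median -0.65, camera adjusted p = 2.9e-04) and 18 of 27 fatty acid oxidation genes, with 4 higher (median -0.65, camera adjusted p = 0.0036). Tricarboxylic acid cycle and respiratory chain genes were higher in 30 of 36 cases (median 0.48, camera adjusted p = 1.4e-15), proximal tubule genes in 13 of 35 with 1 lower (median 0.91, camera adjusted p = 1.9e-06) and NAD biosynthesis genes in 8 of 11 (median 0.70, camera adjusted p = 2.9e-04). The estimated correlation gave adjusted p from 0.28 to 0.64 for these. At sham day 21 tubular injury genes were lower in 22 of 28 cases (median -1.85, camera adjusted p = 4.2e-09). Of the check lists, 4 of 5 adipose tissue genes were lower and Car3 higher at both later days (median -1.46, camera adjusted p = 0.0065, and -1.49, 0.007). These calls ended with an estimated correlation (0.17 and 0.14) and without the filter (-0.09, 0.083, and -0.09, 0.051). Androgen-dependent kidney genes were higher at sham day 3 in 5 of 8 cases and at sham day 21 in 4, with Cyp2d9 lower (median 1.14, camera adjusted p = 0.0065, and 0.97, 0.007). Both calls ended with an estimated correlation (0.25 and 0.26) and after quantile normalization (0.093 and 0.073).

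Between sham days 3 and 21, 5 genes passed the threshold, 2 higher and 3 lower at day 21, and 2284 had an unadjusted p under 0.05. With library weights 1756 passed the threshold. The share of genes separated without overlap was 22.1% (10% by chance). Cyp4a14 fell from 167 ± 12.5 to 17.9 ± 11.0 FPKM (log2 difference -3.39 ± 0.45, limma adjusted p = 0.02) and the keratin Krt7 from 80.6 ± 8.88 to 48.2 ± 4.61 FPKM (-0.73 ± 0.11, limma adjusted p = 0.021). Usp6nl, a GTPase-activating protein, rose from 3.49 ± 0.584 to 6.05 ± 0.482 FPKM (0.66 ± 0.10, limma adjusted p = 0.021). The small nucleolar RNA gene Snord34 went from 3.78 ± 1.03 FPKM at sham day 3 to a value listed at 0 in all 3 libraries of sham day 21, so it has no fold. No marker was past the threshold. Without sham day-3 replicate 1 or 2 no gene was called, without sham day-3 replicate 3 the count was 418, and the calls of Usp6nl, Krt7 and Snord34 also ended without any 1 of the sham day-21 libraries (adjusted p 0.075 to 0.17). Cyp4a14 was at 0.057 without sham day-3 replicate 1 and at 0.088 without replicate 2. Where only the 2 groups were fitted, Cyp4a14, Krt7 and Usp6nl were no longer called (adjusted p 0.27 each). A pseudocount of 5 ended the calls of Usp6nl (0.38, 0.053) and Snord34 (0.099), and the test without the filter that of Snord34 (0.053). camera called 4 lists, the thick ascending limb and distal convoluted tubule (median -0.19, camera adjusted p = 0.047), collecting duct (median -0.22, camera adjusted p = 0.001) and tricarboxylic acid cycle and respiratory chain (median -0.08, camera adjusted p = 0.0013, turned to 0.07 after quantile normalization) down and endothelial cell (median 0.30, camera adjusted p = 0.0095) up, each at adjusted p = 0.96 with an estimated correlation. The thick ascending limb call ended without sham day-3 replicate 1 (-0.12, 0.29) or 3 (-0.21, 0.062) or sham day-21 replicate 1 (-0.20, 0.065) or 3 (-0.11, 0.077). The endothelial cell call ended without sham day-3 replicate 3 (0.11, 0.75) or sham day-21 replicate 2 (0.12, 0.32).

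**Figure D4:**
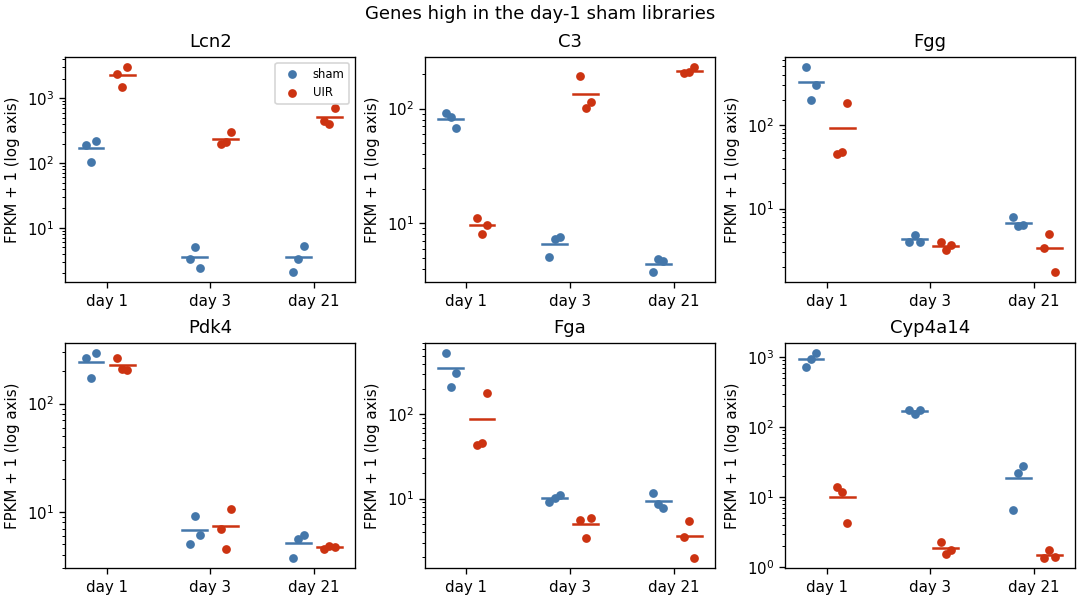
Panels show FPKM + 1 on a log axis for Lcn2, C3, Fgg, Pdk4, Fga and Cyp4a14 in sham and UIR kidneys at days 1, 3 and 21, with points for the 3 libraries of a group and a line at the group mean. Sham day-1 kidneys lie above the later sham kidneys in all 6 genes, as with Fgg at 328 against 3.28 and 5.81 FPKM.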

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

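The tests of explanations and the counts of other splits were chosen after the results were seen, while the differences between days were planned. The following results are flagged since the effect of UIR differed between days by a test of the difference. The difference was past the threshold for 9253 genes between days 1 and 3, 6800 between days 3 and 21 and 10365 between days 1 and 21. It was past it for 18, 12 and 19 of the 20 markers and for 13, 18 and 19 of the 25 lists. Higher at day 1 and lower at day 21 were 240 genes, and the reverse 1721. No expected counts are given, both rest on sham day 1, and 75.2% of day-21 calls were higher, which favours the second. The largest difference was that of C3 between days 1 and 21 (8.68, log2). C3 at day 1 was lower against its own shams (-3.08) but higher (0.83) against the later shams, giving 4.78.

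The libraries were also regrouped, to set the real labels beside other splits. For 6 libraries there are only 10 splits into 3 and 3, too few for a share under 0.05. The real labels gave as many genes as 1 of the 10 splits, the real one, at each day and in each sham comparison, with 8770 genes at day 1 against 2 in the highest other split, 11104 against 0 at day 3 and 11885 against 1 at day 21. In the sham groups the counts were 6258 against 2 between days 1 and 3, 5 against 1 between days 3 and 21 and 5804 against 0 between days 1 and 21. Lists told the labels apart less: 5 of 10 splits gave at least 8 lists at day 1 (highest other 11), 5 of 10 at least 14 at day 3 (highest other 19) and 4 of 10 at least 20 at day 21 (highest other 20). List calls at the preset correlation therefore come up under other splits too. For the differences between days 200 splits of the labels within each day exist, of which 100 were drawn. As many genes came from 2 of 100 between days 1 and 3 (highest other 11146), 6 of 100 between days 3 and 21 (highest other 9518) and 2 of 100 between days 1 and 21 (highest other 11785). A split that mixes the labels of 1 day keeps the effect of the other day, so these counts do not measure chance. To test equal effects at both days, the mean effects of surgery and day were taken out and what remained exchanged between the 12 libraries. Only the real order of 100 gave as many genes each time (highest other 4116, 3525 and 6042). What remained keeps real differences as spread, so this argues only against equal effects in all genes at once.

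Sham day-1 kidneys stood apart from both later sham groups in 4695 genes, 3328 of them higher at day 1. RNA of UIR day-1 kidneys in these libraries is argued against as the whole cause, but not as a part. For 28.0% of genes all 3 sham day-1 values lay outside the range of later sham and UIR day-1 libraries. The share needed would also differ by gene, at 1.46% for Krt20, 7.28% for Lcn2, 18.2% for Havcr1 and 378% for Fgg. An hour of harvest that differed by day stays open: the 16 clock genes moved more between sham days 1 and 3 than 95.6% of 10000 random lists (99.6% between days 1 and 21), though 91.0% without sham day-3 replicate 2, whose clock genes stood apart, and by a median of 0.48 against 0.64 over the genes set apart. A processing batch of the day-1 libraries cannot be told apart from a response to the operation itself, since 74.3% of the genes moved the same way in UIR day-1 kidneys against the later sham kidneys (10.6% the opposite way), as either would give, and the labels name no batch.

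More genes were higher than lower at days 3 and 21, at 76.3% and 75.2% of calls. A few abundant transcripts taking less of the total are argued against as the whole cause. Equal sums over all genes (TPM) gave 84.1% and 80.2%, with medians over all genes of 0.75 and 0.76, and equal sums without the 100 most abundant genes still gave 76.6% and 72.7%, with medians of 0.44 and 0.46. A part of the shift in TPM thus went with these 100 genes. Against the deposited scale, at 0.44 and 0.53, leaving them out moved little at day 3. The split fell with the level of the genes, from 86.7% in the lowest of 4 groups by mean level to 57.3% in the highest at day 3, and from 90.8% to 51.3% at day 21. A scaling that missed a difference in total RNA cannot be told apart from a broad rise, since median-of-ratios scaling gave 51.2% and 52.3% but centres all genes and so fixes this outcome. No biological explanation was tested.

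Proximal tubule transcripts fell at day 21 in all 35 genes of the list. A lower share of proximal tubule cells alone would raise the markers of every other cell type alike. Yet podocyte genes rose by 1.84 and endothelial genes by 1.59 more than collecting duct genes (log2). Intervals (95%) over 10000 resamples of genes, not mice, were 1.14 to 2.56 and 1.02 to 2.22. The same fall of every proximal tubule transcript is argued against too, since the log2 folds had an SD of 1.16 between genes, against a median SE of 0.37, from -0.64 for Slc7a8 to -6.57 for Miox. A lower share of these cells may be joined by a change within them, which is open. Also open is a change in the podocyte, endothelial or collecting duct genes themselves.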

How the results depend on the processing

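Only the later sham control and sums without the 100 top genes were chosen after seeing results. Counts of genes called, except between sham days 3 and 21, stayed within 1.5 times under every alternative. Of 11104 and 11885 calls at days 3 and 21 median-of-ratios scaling kept 7819 and 8757, quantile normalization 7496 and 8208, in direction. Leaving out 1 library at a time gave 8043 to 8660 genes at day 1, 10475 to 10817 at day 3, 11075 to 11668 at day 21, 8637 to 9473 between days 1 and 3, 5651 to 6700 between days 3 and 21 and 9543 to 10511 between days 1 and 21. Sham day 1 gave 4999 to 5803 genes against day 3 and 4522 to 5380 against day 21. The lists called ran from 7 to 8 at day 1, 13 to 15 at day 3 and 18 to 21 at day 21.

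The 5 genes between sham days 3 and 21 became 12 with a pseudocount of 0.1, 2 with a pseudocount of 5, 8 after median-of-ratios scaling, 11 after quantile normalization and 1756 with library weights, and 0 (without sham day-3 replicate 1 or 2) to 418 (without sham day-3 replicate 3) when 1 library was left out. The weights ran from 0.24 for UIR day-1 replicate 3 to 3.99 for UIR day-3 replicate 2, and 2284 genes had an unadjusted p under 0.05. The cause was not tested.

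With an estimated correlation camera called 0 of the 25 lists at day 1, 0 at day 3 and 0 at day 21. fry, which does not compare a list with other genes, called 19 at day 1 and 23 at day 3. At day 3 fry gave the opposite direction to camera for endothelial cell (median 0.44), neutrophil (0.49) and heat shock genes (0.57), and for tubular injury between days 1 and 21 (0.99). The median over all genes was 0.44 at day 3 and 0.51 between days 1 and 21. After quantile normalization the tricarboxylic acid cycle and respiratory chain list between sham days 3 and 21 turned to 0.07, and the cause was not tested.

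Against the later sham libraries day 1 gave 10528 genes and 12 lists, and the differences from day 1 gave 9460 genes to day 3 and 10477 to day 21. The results that reversed under it were C3 (0.83), Cd79a (-0.51), Plin1 (0.01), Cidec (1.33), Plin4 (0.47) and the adipose tissue list (0.01) at day 1. Between days 1 and 3 they were Lcn2 (-3.27), Cdkn1a (-2.2), Cd79a (0.14) and the tubular injury (-0.79) and adipose tissue (-0.31) lists. Between days 1 and 21 they were Havcr1 (-1.38), Lcn2 (-2.11), Sox9 (-0.96), Cdkn1a (-2.29) and the p53 target (-0.05) and adipose tissue (-0.82) lists.

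Among the named genes, leaving out 1 library left 2988 values on the same side of the threshold in the same direction, ended 67 calls and added 11. Quantile normalization ended 9 named-gene calls, a pseudocount of 5 ended 8, TPM and the fit to only the groups compared ended 6 each, as did the test without the filter, median-of-ratios scaling and the later shams as day-1 control ended 5 each, and a pseudocount of 0.1 and equal sums without the 100 most abundant genes ended 1 each. Among the lists, an estimated correlation ended 126 calls, leaving out 1 library 33, quantile normalization 23, fry 16, median-of-ratios scaling 9, the stricter filter 8, no filter 5, TPM, a pseudocount of 5 and the later shams as day-1 control 4 each, a pseudocount of 0.1 3 and library weights 2.

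With the replicate number as a block, the genes called were 8705 at day 1, 11058 at day 3, 11837 at day 21, 9184 between days 1 and 3, 6644 between days 3 and 21 and 10273 between days 1 and 21, and in the sham groups 6133, 6 and 5680, with 8, 14 and 20 lists. Among the named genes and lists the block ended no call and added those of 5 genes and 3 lists. Of 9 pairs of a sham and a UIR library with the same day and number, 1 had a correlation over 0.1, and in 4 of 9 the best partner had the same number, so the numbers do not pair the libraries. The depth is unknown, so what it limits cannot be given, and values near the lowest listed one (0.01 FPKM) carry no stated precision.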

Other observations

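The test in this part was chosen after the result was seen. Genes of fatty acid catabolism were high in sham day-1 kidneys. Of 22 known targets of the fatty acid receptor PPARA, listed after this pattern was seen, 20 passed the filter, and 12 were lower and 1 (Aldh9a1, 0.38) higher in sham day 3 than in sham day 1 (median -0.95), as were 12 and 1 in sham day 21 (median -0.98). Genes listed for a pattern do not test it, so raised PPARA target genes in sham day 1 stay an open explanation. The adipose tissue list moved the same way in 4 of 5 genes (medians -1.46 and -1.49), while Adipoq of fat cells was listed at 0 FPKM in all 3 sham day-1 libraries. The levels do not say whether fasting after surgery, the hour of harvest or the operation raised them.

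Akr1b7 of the adrenal gland list was at 20.47 to 25.4 FPKM in UIR day 1 against 2.42 to 3.13 in sham day 1, and Star at 1.76 to 2 against 0.94 to 1.35. Acta1 of the skeletal muscle list was at 1.89 to 5.01 FPKM in UIR day 3 against 0.05 to 0.18 in sham day 3, but Mylpf at 1.04 to 1.76 against 1.06 to 1.75.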
